A study of Mus musculus with 4 samples.

How the data were processed

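The series measured polyadenylated RNA of single mouse cells by droplet sequencing (10x Genomics 3' chemistry, version 3) in 4 libraries, 1 per condition, on an Illumina HiSeq X with 1 library per lane and 150-base reads, per the labels' protocols. The conditions were epiblast stem cells (EpiSC) before reprogramming, the same reporter line on day 5 and on day 7 of reprogramming towards blastocyst-like hemispheres, and a coculture of C57BL/6 embryonic stem cells (ESC) with a stabilized population positive for MERVL, an endogenous retrovirus that is active in the 2-cell embryo. Each library was placed in its condition by its GEO title. No condition had a replicate, so no test between conditions was made.

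The files analysed here were the authors' list of the cell barcodes they kept, each with a tag naming its library, and the gene annotation of the custom mouse reference, to which the authors had added EGFP and mCherry. Reads were mapped with Cell Ranger 3.1 to a custom mm10 genome, per the submitters' processing notes, which also name Seurat without a version. The annotation was of build GRCm38.p6, per the file headers. The filters by which the authors kept cells are not given in the sources used here, nor is the treatment of doublets in the cell list, and no doublets were called here. Neither file held a measurement per gene and cell: the values in the deposited files were barcodes, library tags, coordinates and gene attributes. Expression levels, UMI counts, clusters and cell classes were not analysed here, and the depth of each library is unknown. All 4 tags matched a library and 0 listed cells were left without one.

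Cells kept were counted per library, with exact Poisson 95% intervals that cover counting error only. Barcodes of 16 bases were compared between the 6 pairs of libraries. The number shared was set against chance for a pool of 7000000 possible barcodes with an exact two-sided Poisson test, and p-values were adjusted over the pairs by the Benjamini-Hochberg method. The pool size was an assumption made before the data were examined, with 3000000 as its alternative.

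The annotation was used to ask which marker genes a method that keeps only reads assigned to 1 gene can count. Marker genes stood in 9 lists fixed before the data were examined, with 129 distinct symbols. The 9 lists were naive, core and primed pluripotency, 2-cell-like genes, trophectoderm, primitive endoderm, fibroblast or feeder cells, X chromosome genes that go with the reporter, and housekeeping genes. For each gene, exon bases that lay in an exon of another gene on the same strand were counted. A gene with at least 1 such base was called as sharing exons. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 9 lists.

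For the 3' ends, the transcript sequences of GENCODE M21, also of build GRCm38, were used where identifier and version were equal to those of the authors' annotation. This held for 109343 of 111079 mouse transcripts (98.4%), which left 30206 genes with a sequence. A genome sequence was not used here. All windows of 150 bases in the last 500 bases of each transcript were looked up, on the sense strand and without mismatches, in every transcript of the other genes. A gene was called not unique when at least 50% of its windows, pooled over its transcripts, occurred in another gene. Copies that differed in every window therefore count as unique, and repeats outside annotated transcripts were not searched. The transgene sequences were not searched either. The search was tested on 500 simulated genes with planted full, partial and altered copies, and 100% of the planted outcomes were recovered.

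The alternatives were distinct barcodes only, the smaller barcode pool, barcode matches with 1 base of difference, protein-coding partners only, overlaps of at least 100 bases, the last 500 bases of each transcript only, windows of 91 and 50 bases, the last 1000 bases, and a limit of 90% of windows. Partners from all gene types of GENCODE M21, and a check of annotated 3' untranslated regions (UTRs), were added after the data had been seen. The genes named are both transgenes, Xist and Tsix, every listed gene missing from the annotation, and up to 10 genes per list with shared exons or a 3' end that was not unique, by the largest share. Other genes named below were chosen after their values were seen. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.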

Results

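Single-cell libraries were made from 4 mouse cultures: EpiSC at the start, cells on day 5 and on day 7 of reprogramming, and a coculture of ESC with MERVL-positive cells. EpiSC are primed pluripotent cells derived from the epiblast, the tissue that gives rise to the embryo proper. The EpiSC line carried the XGFP reporter, an EGFP transgene, and a MERVL::mCherry reporter, and was kept on fibronectin in NDiff227 medium with 12 ng/mL bFGF and 20 ng/mL activin A before reprogramming medium was given. The coculture was kept in 2iLIF, a medium that holds ESC in the naive state, and also carried a MERVL::mCherry reporter. The authors kept 12363 cells in all. There was 1 library per condition with no replicates, so conditions are described and not tested against each other.

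The first comparison asked how many cells each culture contributed. The starting EpiSC library held 2932 cells (exact Poisson 95% interval 2827 to 3040), or 97.7% of the approximately 3000 cells aimed at. The day 5 library held 3212 cells (3102 to 3325), 9.55% more than the EpiSC library, and the day 7 library held 3310 cells (3198 to 3425), 12.9% more. The ESC and MERVL-positive coculture held 2909 cells (2804 to 3017), with an interval that included the 3000 aimed at, as for EpiSC. The highest count was 1.14 times the lowest. The intervals cover counting error only, and differences in loading or in the authors' cell filter between single libraries have no replicate check.

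**Figure D1:**
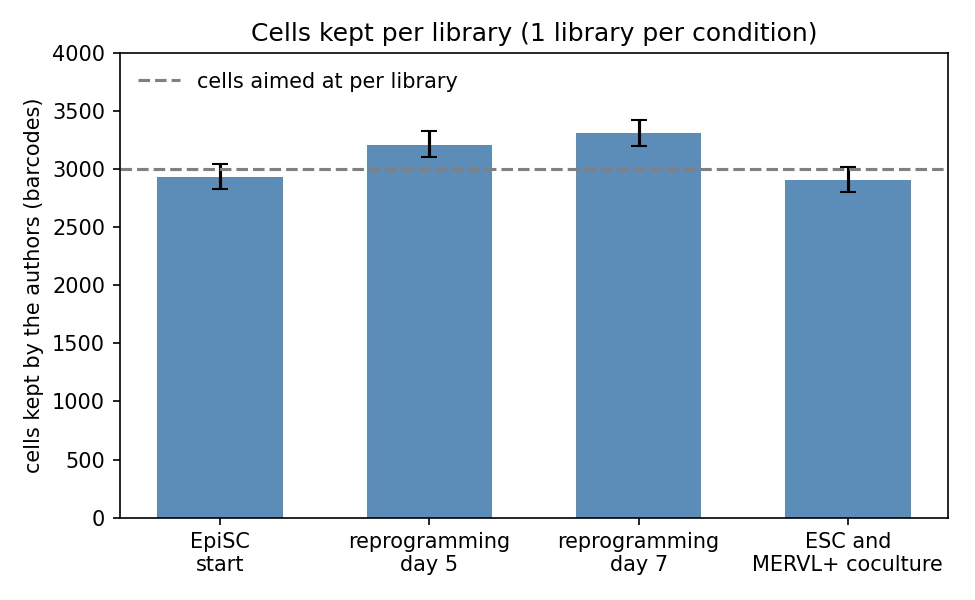
Bars show the number of cells the authors kept in each of the 4 libraries, error bars the exact Poisson 95% intervals, and the dashed line the 3000 cells aimed at per library. The day 5 and day 7 reprogramming libraries lie above the line, at 3212 and 3310 cells, and the intervals of the EpiSC and coculture libraries include it.

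The cells of the 4 cultures were then compared by barcode, since a barcode seen in more than 1 library can come from carry-over or from chance. All barcodes within each library were distinct. Of 12340 distinct barcodes over all libraries, 23 occurred in 2 libraries and 0 in 3 or more. The coculture shared 6 barcodes with the day 5 library and 5 with the EpiSC library, and 0 with the day 7 library. The EpiSC library shared 5 with day 7 and 4 with day 5, and the day 5 and day 7 libraries shared 3. Against a pool of 7000000 barcodes, 8.18 shared barcodes were expected by chance, so that the total was 2.81 times that number (exact Poisson test, two-sided, p = 1.6e-05). With this pool 3 of the 6 pairs passed the test (adjusted exact p = 0.0152 for day 5 and coculture, 0.0247 for EpiSC and coculture, 0.0274 for EpiSC and day 7). With a pool of 3000000 barcodes, 19.1 were expected, the total was 1.21 times that number (exact p = 0.358), and no pair passed, the lowest adjusted exact p being 0.398. Both pool sizes were assumed, so neither result shows by itself whether barcodes were shared beyond chance.

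The study follows reporter transgenes and markers of pluripotent, 2-cell-like and extra-embryonic states, so the next question was which of these genes the authors' annotation lets a 3' count tell apart. EGFP and mCherry, the fluorescent proteins of the reporters, were each annotated as a sequence of their own with 1 transcript of 1 exon, of 924 and 936 bases. Placed on sequences of their own, the transgenes could not overlap a mouse gene in this annotation. Whether they share sequence with each other or with mouse genes was not searched. No gene symbol contained MERVL (0 of 31055 genes), so transcripts of the retrovirus itself have no gene record under that name, while mCherry from its reporter has one. Of the 31053 mouse genes, 22055 were protein-coding, 5499 were long intergenic RNAs and 2805 antisense RNAs. Pseudogenes other than immune receptor segments numbered 0.

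The annotation held 127 of the 129 listed symbols. Both missing symbols were 2-cell-like genes, Zscan4a and Gm4850. In GENCODE M21, Zscan4a is an unprocessed pseudogene on chromosome 7 (GRCm38, 10794242 to 10799057), and Gm4850 is a processed pseudogene on chromosome 1 (31267326 to 31267884). All listed genes of the naive, core and primed pluripotency, trophectoderm, primitive endoderm, fibroblast, X chromosome and housekeeping lists were present.

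Exons shared with another gene on the same strand were found in 5 listed genes. In the trophectoderm list, Gata3, a transcription factor of the trophectoderm, shared 77 exon bases (1.94%) with 9230102O04Rik, and the growth factor receptor gene Fgfr2 shared 314 bases (3.04%) with Ctbp2. The ribosomal protein gene Rpl13a, in the housekeeping list, shared 621 bases (29.4%) with Gm45713. Among 2-cell-like genes, Gm6763 shared 136 bases (10.5%) with Gm21293. Tsix, the antisense partner of Xist, shared 431 bases (7.09%) with Gm26992. The naive, core and primed pluripotency, primitive endoderm and fibroblast lists had 0 such genes. Of all 22055 protein-coding genes, 1135 (5.15%) shared exon bases, and no list differed from the other protein-coding genes (Fisher's exact test, lowest adjusted p = 0.976, for the trophectoderm list with 2 of 17 and the X chromosome list with 1 of 4). Lists of 4 to 35 genes leave wide intervals, such as 1.46% to 36.4% for the trophectoderm list.

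Xist, the long RNA that silences an X chromosome, and Tsix are both on the X chromosome (GRCm38), Xist at 103460375 to 103483217 on the minus strand and Tsix at 103431517 to 103484957 on the plus strand. Their exons overlapped over 1943 bases on opposite strands, and Xist shared 0 exon bases with a gene on its own strand. A count that uses strand can tell them apart there, and one that does not use it cannot.

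Genes whose 3' end is repeated in another gene were found in the 2-cell-like list and in none of the other 8 lists. Of the 35 2-cell-like genes in the annotation, 8 (22.9%, exact binomial 95% interval 10.4% to 40.1%) had at least 50% of their 3' end windows in another gene, against 1088 of 21146 other protein-coding genes (5.15%; Fisher's exact test, two-sided, p = 0.000337, adjusted p = 0.00304). The 8 genes were Zscan4b, Zscan4e, Zscan4f, BB287469, Gm2016, Gm4340, Gm12794 and Gm6763. Annotated 3' UTRs were short for Zscan4b (57 bases), Zscan4e (48) and Zscan4f (129) and absent for Gm12794. Their windows therefore lay mostly outside 3' UTRs, and whether reads would fall at these annotated ends was not tested. The remaining genes had 3' UTRs of 319 (Gm4340 and Gm6763), 840 (Gm2016) and 921 bases (BB287469). The count depended on the setting, with 5 of 35 at a limit of 90% of windows and 13 of 35 with windows of 50 bases. The list was written with several members of some gene families, such as Zscan4, Usp17l and Tdpoz, so its genes are not all independent of each other and the p-value is too small to that extent. Genes with many transcripts can reach 50% of pooled windows less easily, and transcript number was not matched between the list and the other genes. Overlapping gene models also count as shared. In the last 500 bases of a transcript, 1 of 35 listed genes and 845 of 22020 others (3.84%) shared exon bases with another gene.

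Zscan4 genes code for zinc finger proteins of the 2-cell embryo and lie in a cluster on chromosome 7. Zscan4b (10900740 to 10905050) and Zscan4e (11306378 to 11310682) had 100% of their windows in another gene, each mainly in the other. Zscan4f (11397915 to 11402318) had 75.5%, mainly in Zscan4-ps2, which the authors' annotation types as protein-coding in spite of its pseudogene symbol. Of the other 2 listed members, Zscan4c (11005745 to 11010547) had 12.3% of its windows in Zscan4-ps3 and Zscan4d (11161374 to 11166159) had 0%, genes named here after their values were seen. With windows of 50 bases these shares were 59.0% for Zscan4c, which was then not unique, and 27.3% for Zscan4d. The annotated 3' UTRs were short for Zscan4b (57 bases), Zscan4e (48 bases) and Zscan4f (129 bases) and long for Zscan4c (551 bases) and Zscan4d (547 bases). The windows of the genes with short 3' UTRs thus lay mostly outside them.

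**Figure D2:**
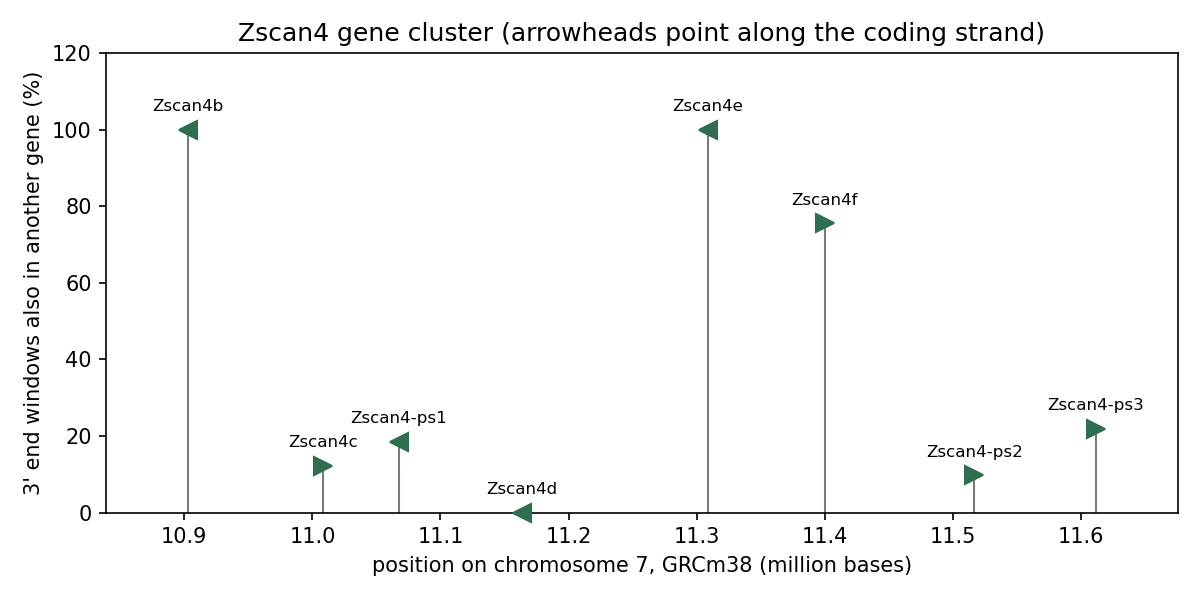
Each point is a gene of the Zscan4 cluster, placed by its position on chromosome 7 (GRCm38) and by the percentage of its 3' end windows of 150 bases that also occur in another gene, with arrowheads along the coding strand. Zscan4b and Zscan4e stand at 100% and Zscan4f at 75.5%, while Zscan4c stands at 12.3% and Zscan4d at 0%, shares that were higher with windows of 50 bases (59.0% and 27.3%).

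The other not-unique genes lay in 3 further regions. On chromosome 12, BB287469 (87816577 to 87820676) had 100% of its windows in Gm4027, and Gm2016 (87874072 to 87877859) had 57.3% in Gm5662. On chromosome 10, Gm6763 (104151497 to 104153965) had 100% and Gm4340 (104194042 to 104196522) had 83.0%, both mainly in Gm8764. On chromosome 4, Gm12794 (101940407 to 101943183) had 100% in Gm12800. A further 8 members had some windows in another gene but under 50%, among them Duxf3, a copy of the Dux transcription factor gene (14.5%, and 46.0% with windows of 50 bases). The remaining 19 had no shared window of 150 bases, among them all 5 listed Usp17l genes, all 4 Tdpoz genes and both Tcstv genes, families named after their values were seen. Shorter windows found some of these again, with 38.2% for Tdpoz1 and 25.5% for Tcstv3 at 50 bases, and with pseudogenes among the partners Tdpoz3 had 34.2%.

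The pluripotency and lineage lists were free of such genes, with 0 of 15 for naive, 0 of 8 for core and 0 of 15 for primed pluripotency, 0 of 17 for trophectoderm, 0 of 13 for primitive endoderm and 0 of 9 for fibroblasts. The X chromosome list had 0 of 3 and the housekeeping list 0 of 10, and the adjusted p was 1 for each of the 8 lists (Fisher's exact test). With lists of this size a count of 0 leaves upper limits of 19.5% (trophectoderm) to 70.8% (X chromosome). At the reads' own length and with partners from the authors' annotation, 83 of 88 distinct genes searched in these lists had no shared window. The highest share was then 16.5%, for Rpl13a. Gapdh had 16.1% and Ppia 7.31%. The signalling genes Lefty1 and Lefty2, neighbours on chromosome 1, had 1.71% and 1.92% in each other. Gapdh, Ppia, Lefty1 and Lefty2 were named after their values were seen. The order depended on the setting. With the shortest windows Gapdh stood highest, at 35.9% against 26.3% for Rpl13a. With partners of all gene types Ppia stood highest (41.9%), followed by Gapdh (33.4%), while Rpl13a stayed at 16.5%. Lama1, Ttr, Acta2 and Xist were not searched, because no transcript of theirs had the same version in both annotations.

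**Figure D3:**
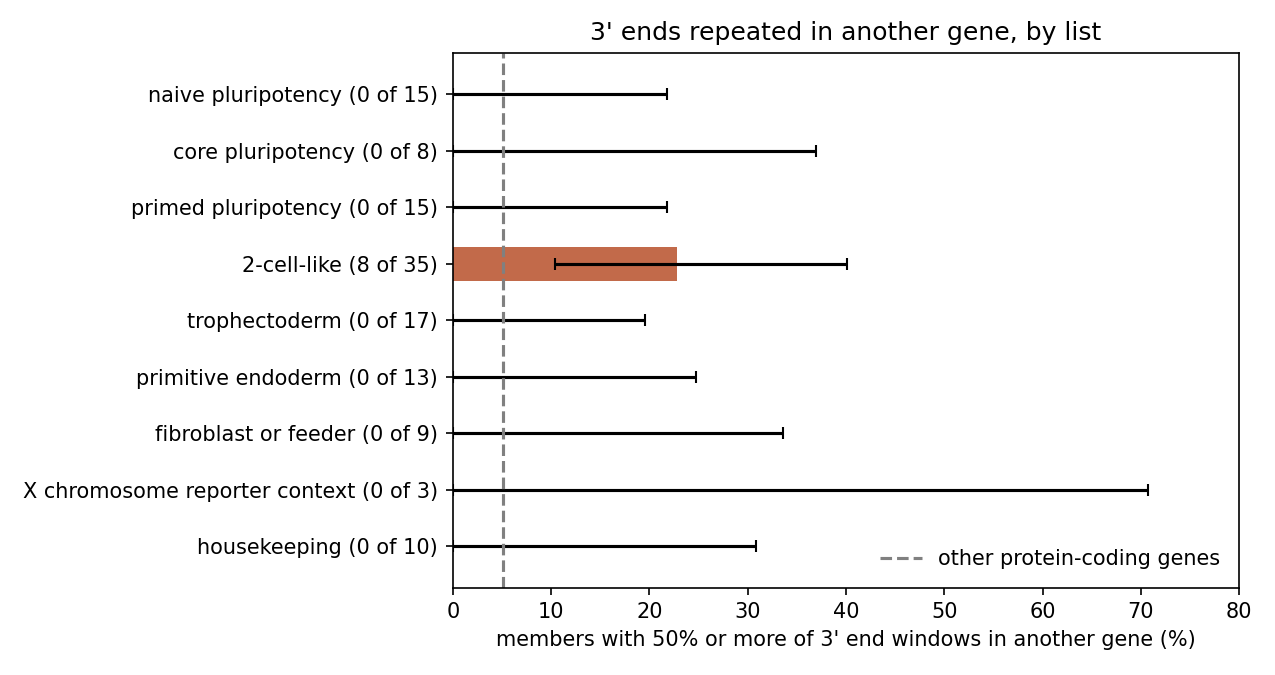
Bars show the percentage of each marker list's searched genes with at least 50% of 3' end windows in another gene, with exact binomial 95% intervals, and the dashed line shows the other protein-coding genes. The 2-cell-like list stands at 22.9% (8 of 35) with an interval above the line at 5.15%, and the other 8 lists stand at 0% with intervals that include it.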

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

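The partner set with all gene types and the check of 3' UTR length were chosen after the data were seen, and the other settings before. Cell counts did not move when only distinct barcodes were counted, since all barcodes within each library were already distinct. The excess of shared barcodes depended on the assumed pool: the ratio to chance was 2.81 with 7000000 barcodes, 2.61 with 1 base of difference allowed (exact p = 4.97e-05) and 1.21 with 3000000 barcodes, where it no longer passed the test. The calls of 3 pairs ended with that pool too, and the ratio for day 5 and day 7 went from 1.98 to 0.847, neither past the test. The larger chance expectation of a smaller pool accounts for these changes by construction. With 1 base of difference allowed the shared barcodes were the same, as no barcodes of different libraries were 1 base apart. That setting therefore gives no separate support for an excess. For shared exons, the trophectoderm count went from 2 to 1 with overlaps of at least 100 bases and to 1 with the last 500 bases of each transcript, and the X chromosome count from 1 to 0 with the last 500 bases. The settings leave out overlaps that are short or far from the 3' end, and no list passed the test in any of them. The 2-cell-like list passed the 3' end test in all 5 alternatives: 13 genes were not unique with windows of 50 bases (adjusted p = 4.08e-06; Zscan4c, Gm5662, Gm2022, Gm20767 and Pramef25 were added), 10 with 91 bases (0.000271), 9 with the last 1000 bases (0.000521), 8 with partners of all gene types (0.00457) and 5 with a limit of 90% of windows (0.0256, Fisher's exact test). Shorter windows are easier to find again and a higher limit is harder to reach, by construction. The alternatives listed before for shares of deposited cell classes and for counts thinned to a fixed number of UMIs were not run, since no such values were analysed here. Of 99 results under an alternative setting, 86 were the same in direction and call, 4 lost their call and 1 reversed. Another 8 counts moved by over 1.5 times, or to or from 0, with no change of call. The 86 are no measure of stability, since many of them could not change. The counts of distinct barcodes are among these, as are lists with 0 genes called, which keep 0 under a narrower rule. The depth of the libraries is unknown, so how far it affected the cells kept, and with them the barcodes shared, was not tested. List sizes set the precision of the shares.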

Other observations

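The test of the excess over read lengths, the test without Gm symbols on the X chromosome and the choice of the gene families named here came after the results were seen. So did the check of 3' UTRs, the partners of all gene types, the interval of the carry-over ratio and the use of single pairs against carry-over. The barcode pool of 3000000 was set before the data were examined, but its use as a test of an explanation came after its result was seen. The other tests were set before.

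The share of genes with repeated 3' ends differed between chromosomes. Repeated here covers both copied sequence and overlapping gene models, which were not set apart. Of protein-coding genes searched, 133 of 183 on the Y chromosome (72.7%, exact binomial 95% interval 65.6% to 79.0%), 136 of 903 on chromosome 14 (15.1%, 12.8% to 17.6%), 124 of 945 on the X chromosome (13.1%, 11.0% to 15.4%) and 41 of 350 on chromosome 18 (11.7%, 8.54% to 15.6%) were not unique, against 839 of 20040 on all autosomes (4.19%). Chromosome 7 had 119 of 1978 (6.02%). On chromosome 18, 36 of 59 protocadherin genes (Pcdh), which code for cell adhesion proteins of neurons and share 3' exons within a cluster, were among them. On the X chromosome they included 25 of 30 Btbd35 genes and 10 of 34 Rhox genes, homeobox genes of the reproductive tract and placenta. On chromosome 14, 115 of 202 genes with a symbol that starts with Gm, as those of predicted gene models do, were not unique, and on the Y chromosome 127 of 165. Families elsewhere were among them too, with 40 of 112 Vmn genes on chromosome 7, 18 of 54 Hist genes on chromosome 13, 14 of 21 Mup genes on chromosome 4 and 12 of 22 Defa genes on chromosome 8.

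The share of genes with repeated 3' ends was higher on the X chromosome than on the autosomes, 13.1% against 4.19% (Fisher's exact test, two-sided, p = 8.51e-27). Whether gene families account for the difference stays open, since any cause would give a higher share and the families were not set apart. Genes with a Gm symbol alone do not account for it: without them the share was 68 of 832 (8.17%) on the X chromosome against 400 of 18865 (2.12%) on the autosomes (Fisher's exact p = 3.05e-19). Predicted gene models under other symbols and overlapping gene models were not set apart. Family members are not independent genes, so both p-values are too small to that extent. A count that keeps only reads of 1 gene may therefore affect a larger share of the annotated X-linked genes than of the autosomal ones. Whether these genes were expressed in these libraries, and what share of X-linked transcripts was left out, was not analysed here. No biological explanation was tested.

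For the 2-cell-like genes with repeated 3' ends, the prediction of nearby copies was met: 8 of 8 (100%) had their main partner on the same chromosome within 5000000 bases, at distances of 6041 to 401328 bases. Only distance was tested, so a tandem order was not shown. Gm2016 and its main partner Gm5662 lie on opposite strands, and Zscan4b and Zscan4e are each other's main partner. Distances were not computed for the other not-unique genes, so nearness is not shown to be particular to this list. The list stood above the other genes at every window length run. It was 37.1% against 7.17% with windows of 50 bases, 28.6% against 6.04% with 91 and 22.9% against 5.15% with 150 (Fisher's exact test, highest adjusted p = 0.00304). An excess was thus present at the reads' own length of 150 bases. This is no separate test of read length, because the result at 150 bases was known when the comparison was chosen. The number of genes called did depend on length, as it must by construction. At 150 bases it was 61.5% of that at 50 bases (8 against 13), which lay between the limits set before and decided neither way. Nearby copies are a property of the genome and the annotation, and no difference between the cultures was tested.

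For the 23 barcodes shared between libraries, a smaller pool of barcodes than 7000000 stays open: a pool of 3000000 was not excluded (exact Poisson p = 0.358), a value already known when the explanation was raised, which does not support it. If all sharing was by chance, the number shared corresponded to a pool of 2489387 barcodes (exact Poisson 95% interval 1659049 to 3927010). That interval includes 3000000 and not 7000000, but it comes from the same 23 barcodes and is no separate evidence. Carry-over between 1 pair of libraries stays open as a part of the number: the highest pair, day 5 and coculture, held 1.60 times its expected share (exact binomial 95% interval 0.627 to 2.97, p = 0.252), and the interval includes both no excess and the limit of 2 set before. Other pairs argue against it as the cause of the whole excess over a pool of 7000000. EpiSC and coculture shared 5 against 1.22 expected (adjusted exact Poisson p = 0.0247), and EpiSC and day 7 shared 5 against 1.39 (0.0274). Besides these 2 and the highest pair no pair passed, and none did with a pool of 3000000. Carry-over spread evenly over all pairs was not tested, and no biological explanation was tested.

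Within libraries, 0 of 19159793 pairs of barcodes were 1 base apart, as were 0 of 57255910 pairs between libraries, so errors in barcodes or beads with 2 barcodes could not be compared between them; 0.214 pairs would be expected within libraries if barcodes were random sequences.

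An annotated 3' UTR was missing in 4 of 35 2-cell-like genes (11.4%; Tdpoz3, Tdpoz4, Gm2022 and Gm12794) against 4.64% of other protein-coding genes, which did not pass the test (Fisher's exact p = 0.0777, adjusted p = 0.699). Counting 3' UTRs under 100 bases as missing gave 8 of 35 (22.9%) against 9.09% (Fisher's exact p = 0.0118, adjusted p = 0.106), which did not pass either. Among genes without a Gm symbol it was missing in 2 of 25 (8.0%) against 2.86% (Fisher's exact p = 0.16), which does not decide whether predicted gene models were involved. With partners of all gene types, pseudogenes included, the shares of the housekeeping genes Gapdh and Ppia were 33.4% and 41.9% of windows, against 16.1% and 7.31% without them. The added partners with the most windows were the processed pseudogenes Gm7336 and Gm10123. Pgk1 went from 0% to 27.7% (Gm5537) and the 2-cell-like gene Tdpoz3 from 0% to 34.2% (Gm4982, an unprocessed pseudogene). These pseudogenes have no record in the authors' annotation, and whether reads from the genes were affected by them was not analysed here.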
